A study of Homo sapiens with 18 samples.

How the data were processed

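RNA was measured by poly(A)-selected, strand-specific sequencing in K562 cells, a human cell line from a chronic myeloid leukaemia. The 18 libraries come from 3 isogenic lines: WT1F8, the control line, and 3D1 and IH2, which carry the K666N substitution of the splicing factor SF3B1 on 1 allele. Each line received the vehicle DMSO or 10 µM stattic, a small-molecule inhibitor of the transcription factor STAT3, for 24 hours. The 6 groups hold 3 libraries each, grouped by line and compound as labelled. Nothing beyond the labels says that replicates were separate cultures.

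The deposited table holds raw counts per Ensembl gene, 1 column per library, made by the authors without normalization. The values are whole numbers from 0 and the library totals differ. The submitters' notes name Trim Galore, STAR 2.4.2a, Picard and featureCounts and the genome build GRCh37. The annotation release, the strand setting and the treatment of reads with several positions or of duplicates are not given in the sources used here. These choices affect genes with near-identical copies (ribosomal proteins, histones, globins, HSPA1A and HSPA1B), so the values of such genes are less certain.

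Of 57820 gene IDs, 41946 had at least 1 count and 39880 had a symbol. A symbol table named 39538 of these and GENCODE 29 a further 342. The 17940 IDs without a symbol held 1.258% of all counts. Symbols carried by more than 1 ID numbered 48, and IDs were never merged. GENCODE 29, which is built on GRCh38, served only for names, biotypes, chromosome, gene order, GC content and length, so no coordinates are given.

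Totals ran from 72.9e+06 to 128.7e+06 counts per library. Between 19136 and 21455 genes had at least 10 counts in a library. Reads without molecular identifiers are not independent molecules, so precision is taken from the spread between libraries and not from counting error. Total count, the share of mitochondrially encoded mRNA and the share of the 10 most abundant genes were compared between arms of a line by two-sided exact permutation tests. With 3 libraries against 3 their smallest p is 0.1.

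Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr (minimum count 10, minimum total 15) kept 22194 genes, 18920 of them with a symbol. TMM factors were used, and 1 quasi-likelihood model with 6 group means and 12 residual degrees of freedom covered all libraries. Its common biological coefficient of variation was 15.8%. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. Log2 fold changes come from edgeR. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Adjusted p-values are from edgeR unless another tool is named. Levels are in CPM, counts scaled by the library total and the TMM factor, as mean ± SD over n = 3 libraries. "Called in both K666N lines" means called in 3D1 and in IH2 in the same direction, and values for "the K666N lines" are the mean contrast of both. A difference of responses was tested as the interaction of line and compound.

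The 40 gene lists were written before the data were examined, as were the comparisons, the tests and the rule for named genes. The rule takes, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among genes with a symbol and a mean of at least 5 CPM, plus up to 4 members of a described list by smallest adjusted p and up to 2 in the other direction. For WT1F8 alone, the 3 libraries of both arms must not overlap. SF3B1, STAT3 and STAT5A are reported in every comparison. The text names a part of the list members that the rule allows. Lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 40 lists, and again with an estimated correlation. Members called are counted over all tested genes and "adjusted over the list alone". Of the 48 replication-dependent histones, 21 IDs were matched, so that list is partial.

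The test was run on simulated data over all 22194 genes. For stattic in WT1F8 it recovered 26.7%, 60.3% and 88.1% of genes changed by 0.5, 1 and 2 on the log2 scale, with 5 of 124 calls false. For the difference of responses of 3D1 and WT1F8 it recovered 3.2%, 41.8% and 66.2%, with 6 of 83 calls false. For 3D1 against WT1F8 in DMSO it recovered 11%, 35.9% and 71.4%, with 3 of 74 false. The list test called a proteasome list raised by 0.3 (adjusted p = 5.86e-43) and 0 of the other 39 lists. Simulated genes were drawn independently, so this does not show how the list test holds for correlated genes. In the real WT1F8 libraries, splits other than the true one called 5 to 18 lists. In 20 simulations without any effect or any difference between lines, comparisons sharing the WT1F8 libraries gave a median of 0 shared calls. The highest was 1, for the responses.

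Replicate numbers carried a common signal. In 18 of 18 libraries the deviation from the group mean correlated best with a library of the same number, and every pair correlated above 0.1 in 6 of the 9 pairs of arms compared here. A fit with the replicate number as a term is therefore given wherever it changes a call or a count. Other alternatives were DESeq2 1.42.0, RLE factors, no factors, a filter of at least 1 CPM in at least 3 libraries, no filter, a fit on the libraries of the comparison only, 1 summed library per line, and leaving out each library or each replicate number. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest. Splicing was not analysed here, since gene counts do not show which splice sites or which SF3B1 allele were used.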

Results

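Gene expression was measured by RNA sequencing in 18 libraries of K562 cells, a human chronic myeloid leukaemia line with erythroid features. The libraries form 6 groups of 3. WT1F8 is the control line, and 3D1 and IH2 are lines with a K666N substitution in 1 allele of SF3B1, the splicing factor that recognises the branch point. Each line was exposed for 24 hours to DMSO or to 10 µM stattic, an inhibitor of STAT3 activation. Total counts were 91.8e+06, 82.9e+06 and 73.9e+06 in the 3 WT1F8 DMSO libraries and 86.4e+06, 98.0e+06 and 82.8e+06 in the WT1F8 STATTIC libraries. They were 73.9e+06, 102.5e+06 and 81.4e+06 for 3D1 in DMSO, 101.7e+06, 79.7e+06 and 128.7e+06 for 3D1 in stattic, 81.8e+06, 72.9e+06 and 91.4e+06 for IH2 in DMSO, and 89.2e+06, 92.8e+06 and 78.1e+06 for IH2 in stattic. Mitochondrially encoded mRNAs held 1.92% to 3.54% of the counts and the 10 most abundant genes 4.72% to 6.25%. Exact permutation tests between the arms of each line gave two-sided p from 0.1 to 0.8 for total count and both shares, where 0.1 is the smallest p that 3 libraries against 3 can give. These tests ignore replicate numbers. At each number the share of the 10 most abundant genes was lower under stattic in 3D1 (means 5.47% against 6.04%) and IH2 (5.06% against 5.67%), but not in WT1F8. The share of mitochondrial rRNA was lower in the same pairs, for example 0.54% against 0.82% in 3D1 replicate 1. The first principal components held 39.7% and 25.1% of the variance.

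The edited gene and the target of the compound were read in every comparison. SF3B1 (ENSG00000115524.11) stood at 306 ± 26.6 CPM (SD, n = 3) in WT1F8, 314 ± 32.8 CPM in 3D1 and 283 ± 18.6 CPM in IH2 under DMSO, and it was not called in any comparison. STAT3 (ENSG00000168610.10) was 313 ± 16.9 CPM in WT1F8 under DMSO and 244 ± 19.0 CPM under stattic, with a log2 fold change of -0.36 ± 0.09 (SE, adjusted p = 0.0642). That WT1F8 value was called with the replicate number in the model (adjusted p = 0.0189), with the filter at 1 CPM (adjusted p = 0.0413) and by DESeq2 (adjusted p = 0.00619). STAT3 fell under stattic in 3D1, from 294 ± 17.7 to 243 ± 5.93 CPM (log2 fold change -0.27 ± 0.09, adjusted p = 0.038), and in IH2, from 246 ± 22.7 to 200 ± 15.3 CPM (-0.30 ± 0.09, adjusted p = 0.0184). Its call in both K666N lines was lost in 7 of the 12 fits that left out 1 library. STAT5A (ENSG00000126561.12) fell under stattic in IH2, from 535 ± 36.8 to 397 ± 82.8 CPM (log2 fold change -0.43 ± 0.12, adjusted p = 0.0155), and was not called in 3D1 (-0.05 ± 0.12) or WT1F8 (-0.08 ± 0.12). Between lines in DMSO, STAT3 was lower in IH2 (246 ± 22.7 CPM) than in WT1F8 (313 ± 16.9 CPM), with 3D1 between them (294 ± 17.7 CPM). With 1 summed library per line, the K666N lines differed from WT1F8 by -0.20 for STAT3 and 0.01 for STAT5A on the log2 scale. Neither gene was called in both K666N lines against WT1F8 in any fit that left out 1 library. Stattic acts on STAT3 protein, whose phosphorylation is not measured by RNA counts.

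**Figure D1:**
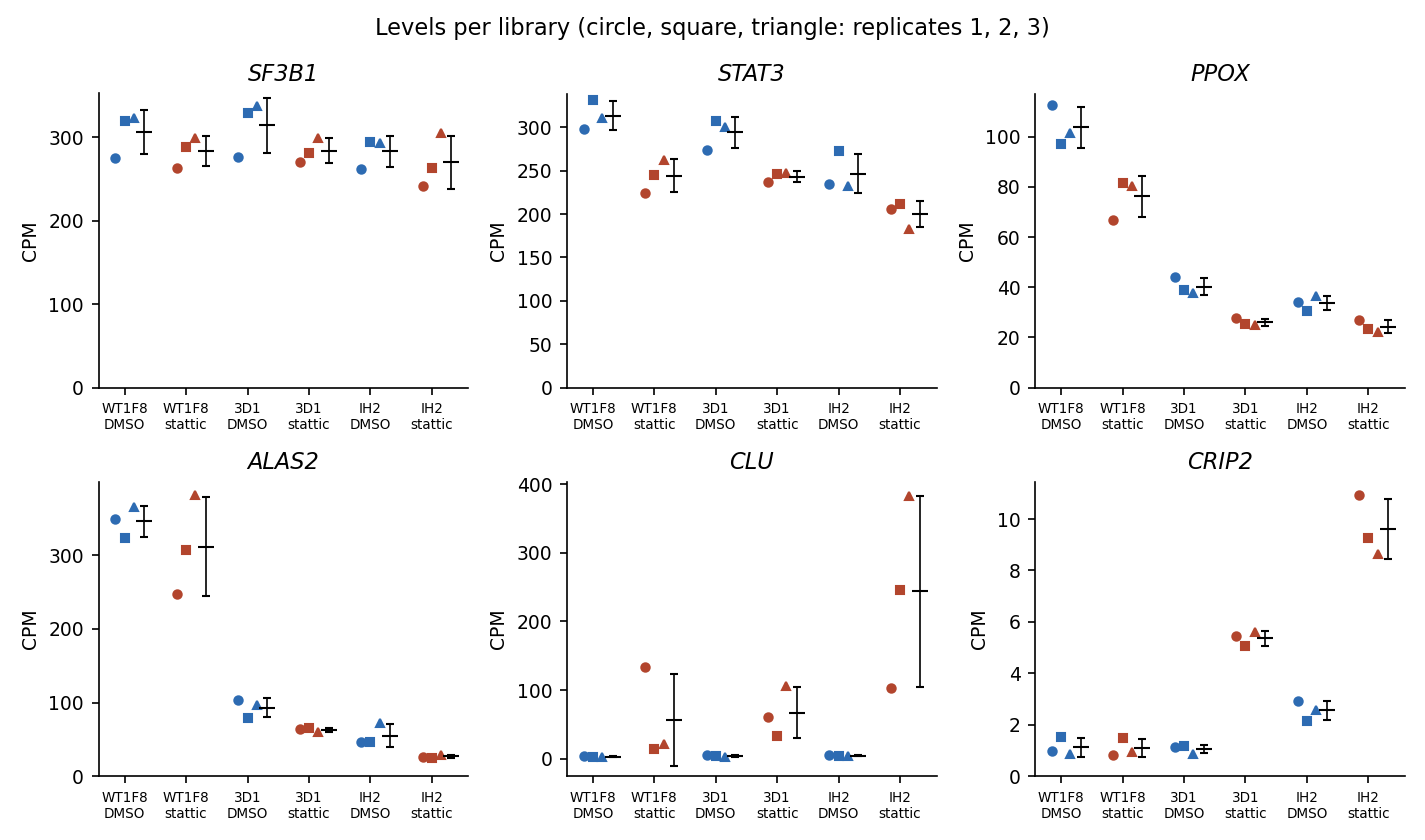
Levels of 6 genes in CPM (vertical axes) in the 6 groups (horizontal axes). Points are libraries, black bars the mean ± SD (n = 3). SF3B1 lies between 270 and 314 CPM on average in every group, while PPOX and ALAS2 are lower in both K666N lines than in WT1F8.

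The first comparison asked what stattic did in the control line. The largest rise was in CLU (ENSG00000120885.15), which encodes clusterin, a secreted chaperone. It went from 3.39 ± 0.839 to 56.4 ± 67.4 CPM (log2 fold change 4.05 ± 0.71, adjusted p = 0.0149), with 134.2 CPM in STATTIC replicate 1 against 13.98 and 21.11 CPM in replicates 2 and 3. ANKRD33 rose from 6.46 ± 2.51 to 29.5 ± 18.1 CPM, ACVRL1, a receptor of the TGF-beta family, from 10.2 ± 2.52 to 34.3 ± 19.0 CPM, and EPAS1, which encodes the hypoxia-inducible factor HIF-2 alpha, from 22.8 ± 5.2 to 54.9 ± 24.3 CPM. S100A10, FAM43A, KRT15, KCP, GBGT1 and ACE completed the 10 largest rises, with log2 fold changes from 1.23 to 1.38. The genes that fell most were APLNR, the apelin receptor, from 54.8 ± 13.2 to 22.5 ± 6.08 CPM, PDE11A, a phosphodiesterase, from 45.8 ± 11.7 to 19.9 ± 4.47 CPM, and PRF1, which encodes perforin, from 16 ± 1.94 to 7.06 ± 2.03 CPM. AQP1, CAMK2N1, ADD2, BCYRN1, LTBP1, ADGRV1 and MNX1 followed, with log2 fold changes from -0.96 to -0.82.

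Grouped by list, 7 of the 41 measured NRF2 targets rose and 0 fell, with 34 not called (11 higher and 1 lower adjusted over the list alone). Among them, the detoxifying enzymes AKR1C1 rose from 63.6 ± 5.61 to 134 ± 5.91 CPM and NQO1 from 83.9 ± 10.4 to 174 ± 33.1 CPM, and the ferritin light chain gene FTL rose from 3070 ± 200 to 5050 ± 599 CPM. The list was called higher (adjusted p = 8.14e-05 by camera, adjusted p = 0.501 with an estimated correlation). Of 24 myeloid markers, 3 rose and 21 were not called (9 higher and 1 lower adjusted over the list alone). These included SPI1, which encodes the myeloid transcription factor PU.1 (31.2 ± 0.593 to 56.7 ± 17 CPM), and the surface receptor CD33 (24.0 ± 2.86 to 36.7 ± 5.51 CPM). The median was 0.63 (adjusted p = 2.43e-05, adjusted p = 0.253 with an estimated correlation). Of 39 autophagy and lysosome genes, 3 rose, the lysosomal protease CTSL and the autophagy receptor SQSTM1 among them, and 36 were not called (6 higher and 1 lower adjusted over the list alone, adjusted p = 0.000779, adjusted p = 0.519 with an estimated correlation).

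Glycolysis genes were called lower as a list with a median of -0.27 (adjusted p = 3.69e-08, adjusted p = 0.501 with an estimated correlation). Of 27 members 1 fell, GAPDH, from 2330 ± 112 to 1620 ± 308 CPM, 26 were not called, and 13 were lower adjusted over the list alone. Cholesterol and fatty acid synthesis genes had a median of -0.25 (adjusted p = 6.47e-06, adjusted p = 0.519 with an estimated correlation), and 1 of 31 fell, the desaturase FADS2, with 7 lower and 1 higher adjusted over the list alone. No member was called among 49 genes of the ATF4 stress response (median -0.28, adjusted p = 9.22e-07, adjusted p = 0.601 with an estimated correlation), 34 hypoxia genes (-0.30, adjusted p = 1.06e-05, adjusted p = 0.601 with an estimated correlation) or 51 G1/S genes (-0.14, adjusted p = 1.67e-07, adjusted p = 0.519 with an estimated correlation), where 1, 2 and 4 were lower adjusted over the list alone. The 34 STAT3 targets (1 lower, 33 not called, adjusted p = 0.198) and 23 STAT5 targets (1 lower, 22 not called, adjusted p = 0.101) were not called as lists. The 1 member that fell is in both, CCND2, which encodes cyclin D2, from 44.2 ± 6.1 to 29.8 ± 2.67 CPM, and 1 higher and 2 lower STAT3 targets and 1 lower STAT5 target were called adjusted over the list alone. In all, 16 lists were called with the preset correlation and 0 with the estimated one. Erythroid genes (median -0.20), replication-dependent histones (-0.48) and serine and one-carbon genes (-0.25) were lower in WT1F8 too. With the replicate number in the model and the preset correlation, camera gave adjusted p = 1.18e-05, 7.76e-06 and 9.11e-06.

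In WT1F8, edgeR called 143 of 22194 genes, 111 higher and 32 lower, and 2920 had an unadjusted p under 0.05. With the replicate number in the model the count was 648 (358 higher, 290 lower, all 143 among them), and DESeq2 called 611 (139 shared). With only the 6 libraries of this comparison it was 2, and without replicate numbers 1, 2 and 3 in all groups it was 3, 29 and 1. Without WT1F8 DMSO replicates 1, 2 and 3 in turn the count was 42, 67 and 20, without WT1F8 STATTIC replicates 1, 2 and 3 it was 18, 269 and 94, and of the 33 called genes followed through the alternatives 4 (AKR1C1, NQO1, PDE11A, ADGRV1) were called in all 6 of those fits.

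The next comparison asked what stattic did in both lines with K666N. The immediate early genes FOSB and ARC, the stress chaperones CRYAB and HSPA6, and RASD1 and CLU were among the 10 largest rises. CLU went from 4.22 ± 1.38 to 67.1 ± 37.0 CPM in 3D1 and from 4.42 ± 0.624 to 244 ± 139 CPM in IH2. RASD1, CLU, ARC and FOSB had mean log2 fold changes of 5.18, 4.89, 4.86 and 4.28. IH2 STATTIC replicate 3 stood apart in these genes, with FOSB at 886 CPM against 17.6 and 82.4 CPM in replicates 1 and 2 of that group, ARC at 350 against 9.76 and 65.3 CPM, and RASD1 at 81.7 against 1.56 and 9.89 CPM. PI16, ANKRD33, KRT15 and S100A10 completed the 10. S100A10 rose from 2.31 ± 0.229 to 13.7 ± 3.04 CPM in 3D1 and from 2.83 ± 0.187 to 13.4 ± 1.15 CPM in IH2. As a list, heat shock genes were not called (adjusted p = 0.402 by camera with the replicate number in the model). In 3D1 the chaperone gene HSPA1A was 307, 326 and 518 CPM in DMSO and 306, 265 and 570 CPM in stattic. DNAJB1 was 183, 169 and 256 CPM there in DMSO and 170, 157 and 179 CPM in stattic.

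Genes of red cells were among the largest falls. The embryonic and minor globin genes HBM (mean log2 fold change -2.34) and HBZ (-2.06), the globin pseudogene HBBP1 (-1.69) and PKLR (-2.23), the red cell pyruvate kinase, were among the 10. PKLR went from 58.4 ± 5.77 to 13.4 ± 3.77 CPM in 3D1 and from 55.8 ± 15 to 11 ± 4.24 CPM in IH2. HBBP1 has close paralogs, so its value is uncertain. ACTL8, DERL3, APLNR, MNX1 and the membrane skeleton gene ADD2 were also among the 10, with means from -1.74 to -1.32. Of 48 erythroid genes 20 fell, 1 rose and 27 were not called (27 lower and 1 higher adjusted over the list alone). Among them NFE2, TFR2 and GYPC fell by means of -0.65, -0.70 and -0.59, and EPB41 rose (0.38 ± 0.08). The list median was -0.47 (adjusted p = 2.55e-09, adjusted p = 0.285 with an estimated correlation), against -0.20 in WT1F8. Of 35 heme and iron-sulfur cluster genes 9 fell, 1 rose and 25 were not called (20 lower and 3 higher adjusted over the list alone), with ALAS2 and PPOX among the lower ones and ALAD higher (adjusted p = 9.13e-05, adjusted p = 0.221 with an estimated correlation).

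Lists of energy production and growth had lower medians, called with the preset correlation only. Of 77 nuclear-encoded oxidative phosphorylation genes 30 fell, 0 rose and 47 were not called (66 lower and 2 higher adjusted over the list alone). NDUFV1 of complex I went from 444 ± 37.9 to 274 ± 18.4 CPM in 3D1 and from 362 ± 7.69 to 230 ± 11.5 CPM in IH2, and ATP5MC3 (-0.59 ± 0.08) and UQCR10 (-0.61 ± 0.08) also fell. The median was -0.33 (adjusted p = 3.34e-18, adjusted p = 0.301 with an estimated correlation). Of 78 cytosolic ribosomal protein genes 7 fell and 71 were not called (55 lower adjusted over the list alone, median -0.24, adjusted p = 5.88e-14, adjusted p = 0.413 with an estimated correlation), with RPS10, RPS26 and RPL17 as examples, a family with many pseudogenes. Of 51 G1/S and replication genes 18 fell and 33 were not called (40 lower and 1 higher adjusted over the list alone), among them POLA1 (-0.58 ± 0.06), RRM2 (-0.55 ± 0.06) and CDC45 (-0.57 ± 0.07), with adjusted p = 1.47e-13 and adjusted p = 0.221 with an estimated correlation. Ribosome biogenesis and MYC target genes had 10 of 45 lower and 35 not called (24 lower adjusted over the list alone), including NPM1, FBL and NOLC1 (adjusted p = 1.98e-07, adjusted p = 0.413 with an estimated correlation). Of 79 spliceosome genes 20 fell and 59 were not called (39 lower and 3 higher adjusted over the list alone), with SF3B5 and DDX46 as examples (adjusted p = 3.3e-07, adjusted p = 0.301 with an estimated correlation). DNA repair genes had 10 of 61 lower, 1 higher and 50 not called (30 lower and 5 higher adjusted over the list alone), with RAD54L (-0.62 ± 0.07) and FANCD2 (-0.43 ± 0.05) lower (adjusted p = 5.65e-05, adjusted p = 0.221 with an estimated correlation).

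Some metabolic genes fell. Of 25 serine and one-carbon genes 8 fell, 1 rose and 16 were not called (15 lower and 1 higher adjusted over the list alone), with MTHFD1L, CBS and SHMT2 lower by means of -0.91, -0.70 and -0.54 (adjusted p = 7.16e-06, adjusted p = 0.221 with an estimated correlation). Of 31 cholesterol and fatty acid genes 8 fell, FADS1, FASN and ACLY among them, 1 rose, PMVK, and 22 were not called (17 lower and 1 higher adjusted over the list alone, adjusted p = 1.86e-05, adjusted p = 0.413 with an estimated correlation). Of 27 glycolysis genes 7 fell, GAPDH and LDHB among them, 2 rose, PKM among them, and 18 were not called (15 lower and 4 higher adjusted over the list alone, adjusted p = 0.00141, adjusted p = 0.413 with an estimated correlation). Of 20 measured replication-dependent histone genes 3 fell, H2BC11 and H2BC5 among them, 1 rose and 16 were not called (17 lower and 1 higher adjusted over the list alone, adjusted p = 3e-05, adjusted p = 0.413 with an estimated correlation).

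Some signalling, lysosomal and myeloid genes rose, and their lists were called with the preset correlation only. Of 31 immediate early genes 6 rose and 25 were not called (23 higher and 1 lower adjusted over the list alone), including NR4A1, a nuclear receptor (5.84 ± 1.01 to 17.3 ± 3.69 CPM in 3D1, 15 ± 2.24 to 64.0 ± 24.7 CPM in IH2), and BTG2, with a list median of 0.87 (adjusted p = 8.54e-06, adjusted p = 0.413 with an estimated correlation). Of 23 ERK output genes 7 rose and 16 were not called (13 higher and 2 lower adjusted over the list alone), with PHLDA1 at 1.49 ± 0.14 and the phosphatase gene DUSP5 at 1.27 ± 0.15 (adjusted p = 0.000782, adjusted p = 0.234 with an estimated correlation). Of 39 autophagy and lysosome genes 11 rose and 28 were not called (20 higher and 2 lower adjusted over the list alone). SQSTM1 rose from 294 ± 64.9 to 614 ± 79.7 CPM in 3D1 and from 377 ± 34.3 to 948 ± 99.1 CPM in IH2, and CTSB and NEU1 rose as well (adjusted p = 5.65e-05, adjusted p = 0.301 with an estimated correlation). Of 24 myeloid markers 7 rose, ITGAX (1.85 ± 0.20) and SPI1 (0.81 ± 0.12) among them, and 17 were not called (12 higher and 1 lower adjusted over the list alone, adjusted p = 0.000802, adjusted p = 0.221 with an estimated correlation). Of 37 interferon-stimulated genes 7 rose, IFI16, ISG20 and GBP2 among them, 1 fell, IFITM1, and 29 were not called (14 higher and 4 lower adjusted over the list alone, adjusted p = 0.0188, adjusted p = 0.344 with an estimated correlation). Of 41 NRF2 targets 7 rose, among them AKR1C1, NQO1 and OSGIN1, 6 fell, TKT among them, and 28 were not called (16 higher and 7 lower adjusted over the list alone, adjusted p = 0.0393, adjusted p = 0.418 with an estimated correlation). That list was not called without IH2 STATTIC replicate 3 (adjusted p = 0.0967).

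As lists, STAT target genes did not move one way. Of 34 STAT3 targets 5 rose, TIMP1, IL4R and the cytokine receptor chain IL6ST among them, 2 fell, CCND2 among them, and 27 were not called (16 higher and 8 lower adjusted over the list alone, adjusted p = 0.215). CCND2 fell from 41.2 ± 5.59 to 25.6 ± 3.02 CPM in 3D1 and from 21 ± 0.2 to 10.7 ± 0.798 CPM in IH2. Of 23 STAT5 targets 2 rose, DUSP5 among them, 2 fell, CCND2 and the signalling inhibitor SOCS2, and 19 were not called (9 higher and 8 lower adjusted over the list alone, adjusted p = 0.858). The STAT5 median was -0.02 and its mean 0.09, and without normalization factors the median was 0.07. With the replicate number in the model neither list was called (adjusted p = 0.23 and 0.802 by camera). Outside the rule, the STAT-regulated genes PIM1 and CISH were lower under stattic at each replicate number in every line. In 3D1, PIM1 went from 395, 819 and 1180 to 327, 301 and 597 CPM. CISH in WT1F8 replicate 1 hardly moved (77.8 to 77.7 CPM). Test values for PIM1 and CISH are not given here, and these genes do not stand for the STAT lists, which were not called. Of 31 genes known as missplicing targets of mutant SF3B1, 4 fell (TPP2, SERBP1 and PPOX among them), 2 rose (ORAI2 among them) and 25 were not called (13 lower and 5 higher adjusted over the list alone, adjusted p = 0.00614, adjusted p = 0.301 with an estimated correlation).

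Stattic changed 3743 genes in 3D1 (1993 higher, 1750 lower) and 5290 in IH2 (2848 higher, 2442 lower), and 2256 in both in the same direction (1168 higher, 1088 lower), with 24 lists called. The balance depends on the scale, since without normalization factors 79.6% of the genes called in 3D1 and 64.8% of those in IH2 were higher, against 53.2% and 53.8% with TMM factors. The block on replicate number gave 5483 genes in 3D1, 6987 in IH2 and 3392 in both lines and added hypoxia (adjusted p = 0.0464), the unfolded protein response (adjusted p = 0.046) and NF-kB targets (adjusted p = 0.0456) to the lists. Without 3D1 DMSO replicate 2 or 3 the count for both lines was 1363 or 1322, and without 3D1 STATTIC replicate 1 or 3 it was 1379 or 1284. The counts for 3D1 alone in those fits were 1957, 1914, 1972 and 1922, and 64 of the 87 called genes followed through the alternatives were called in all 12 fits that left out 1 library, the exceptions including RASD1 (lost in 9), EPB41 (10), ORAI2 (8), H2BC5 (7), FOSB and IFITM1 (6 each) and ALAS2 (5).

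The responses of the lines overlapped. Of the 111 genes higher in WT1F8, 100 were also higher in 3D1 and 95 in IH2, where independent lists would share 10 and 14.2. Of the 32 lower genes, 21 and 22 were shared, against 2.5 and 3.5. These pairs share no library. Across 10734 genes of at least 5 CPM, which are not independent replicates, the response of 3D1 correlated with that of WT1F8 with Pearson r = 0.736 (Spearman 0.673), that of IH2 with r = 0.616 (0.585), and those of 3D1 and IH2 with r = 0.739 (0.75). In all 3 lines, 106 genes changed in the same direction, 90 higher and 16 lower, including CLU, AKR1C1, NQO1, SQSTM1, CTSL and SPI1 among the higher and APLNR, MNX1, CCND2 and GAPDH among the lower. The count was 447 with the block on replicate number and 401 by DESeq2. It was 30, 48 and 11 without WT1F8 DMSO replicates 1, 2 and 3, 11 and 179 without WT1F8 STATTIC replicates 1 and 2, and 168 without IH2 STATTIC replicate 3.

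**Figure D2:**
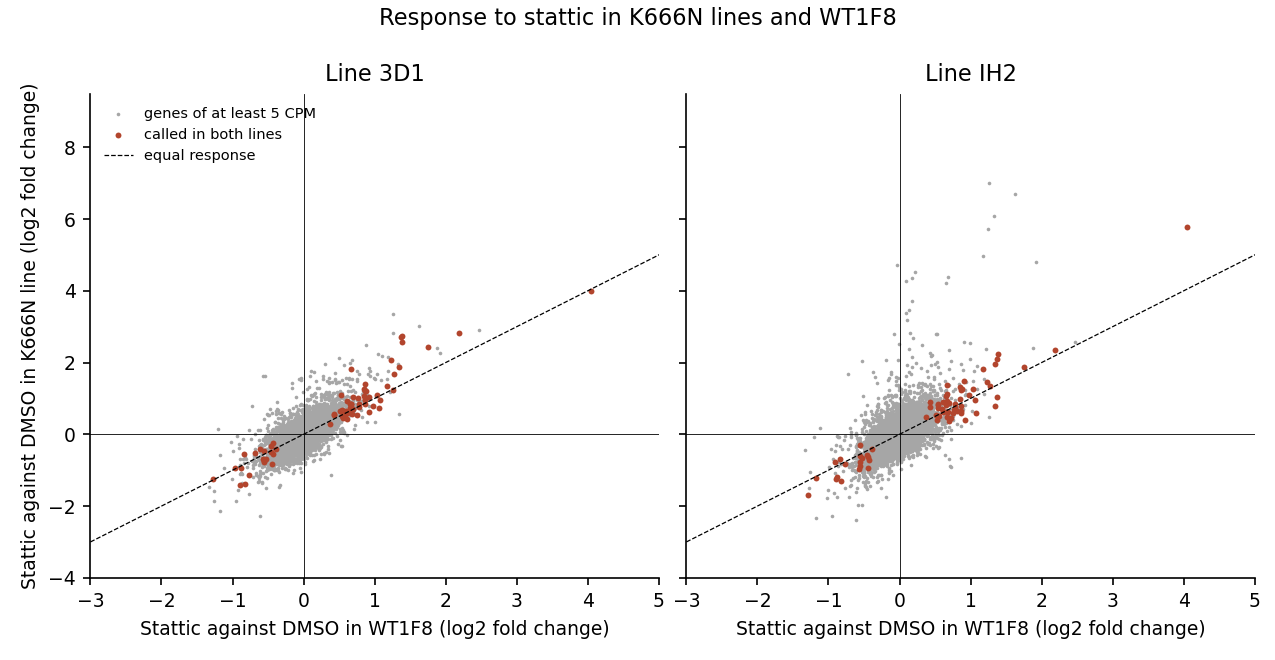
Log2 fold change under stattic of genes of at least 5 CPM in WT1F8 (horizontal axes) against 3D1 (left, vertical axis) and IH2 (right). Red points were called in both lines plotted, and the dashed line marks an equal response. The major axes of the points are steeper than the dashed line, with slopes of 1.87 for 3D1 (r = 0.736) and 2.72 for IH2 (r = 0.616). Such an axis steepens with any added spread in the K666N line.

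The third comparison set the K666N lines against WT1F8 in DMSO. Genes that were nearly silent in WT1F8 and on in both K666N lines led the rises. ARHGAP15, a GTPase activator, was 0.38 ± 0.12 CPM in WT1F8, 41 ± 7.26 CPM in 3D1 and 26.4 ± 2.11 CPM in IH2. DIRAS3, an imprinted Ras family gene, was 0.987 ± 0.175 CPM against 28.4 ± 2.7 and 30.1 ± 2.83 CPM, and IL1RAP, the accessory chain of the interleukin 1 receptor, 0.633 ± 0.18 CPM against 9.91 ± 1.61 and 10.5 ± 1.18 CPM. MUC19, AGMO, ENC1, EPHB6, PRDM9, RBPMS2 and ITGBL1 were the others, with mean log2 fold changes from 3.79 to 5.17. SNHG14, a long noncoding RNA, held 4750 counts in the 3 WT1F8 libraries, 1 count in 3D1 and 34 in IH2. CCDC120 was 11.7 ± 1.27 CPM in WT1F8, 0.0415 ± 0.0269 CPM in 3D1 and 6.78 ± 0.285 CPM in IH2, so its mean rests on 3D1. CECR2, COBLL1, MALT1, ACTL8, ALDH1L1, DHRS2, CYFIP2 and ANKRD20A19P, a pseudogene whose value is uncertain, made up the rest of the 10 largest falls, and DHRS2 was 585 ± 17.9 CPM in WT1F8, 29.6 ± 4.39 CPM in 3D1 and 54.0 ± 8.07 CPM in IH2.

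Transcripts known to be missplicing targets of mutant SF3B1 were lower for 9 of 31, higher for 2 and not called for 20 (10 lower and 5 higher adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.393). PPOX (ENSG00000143224.13), an enzyme of heme synthesis, was 104 ± 8.05 CPM in WT1F8, 40.2 ± 3.4 CPM in 3D1 and 33.6 ± 2.88 CPM in IH2 (adjusted p = 2.01e-08 and 1.81e-09). TTI1 (-0.74 ± 0.06) and SKIC2 (-0.65 ± 0.08) were also lower and CRNDE was higher (0.74 ± 0.16). Of 48 erythroid genes 13 were lower, 0 higher and 35 not called (32 lower and 2 higher adjusted over the list alone), with a median of -0.60 (adjusted p = 1.39e-07, adjusted p = 0.996 with an estimated correlation). Outside runs of neighbouring genes that shifted together, the median was -0.46 (SD of members 1.03, n = 35, against SD 0.94 for all). The list stayed called there (adjusted p = 1.34e-05 by camera with the preset correlation). ALAS2, the erythroid enzyme of the first step of heme synthesis, was 346 ± 21.1 CPM in WT1F8, 92.9 ± 13 CPM in 3D1 and 55.1 ± 15.3 CPM in IH2, the embryonic globin HBE1 3250 ± 929 CPM against 276 ± 44.0 and 651 ± 226 CPM, and TMCC2 and RHAG were lower too. Of 35 heme and iron-sulfur genes 6 were lower, among them FECH and SLC25A37, 3 higher, ISCA1 among them, and 26 not called (11 lower and 7 higher adjusted over the list alone, adjusted p = 0.726). The 27 heme and iron-sulfur genes outside those runs had a median of -0.021, against -0.046 for all. Members inside the runs, lower ones included, may have moved with their neighbours.

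Of 78 cytosolic ribosomal protein genes 18 were higher, 0 lower and 60 not called (40 higher adjusted over the list alone), with a median of 0.25 (adjusted p = 3.01e-09, adjusted p = 0.996 with an estimated correlation). RPL35 was 411 ± 40 CPM in WT1F8, 909 ± 103 CPM in 3D1 and 689 ± 32 CPM in IH2, and RPS10 and RPL7A were higher as well. Nuclear-encoded oxidative phosphorylation genes had 8 of 77 higher and 69 not called (10 higher and 1 lower adjusted over the list alone), among them ATP5F1D, NDUFA8 and NDUFV2 (adjusted p = 0.00957, adjusted p = 0.996 with an estimated correlation). Proteasome genes had 4 of 43 higher, PSMD5 and PSMB7 among them, 1 lower, PSMD1, and 38 not called (8 higher and 2 lower adjusted over the list alone, adjusted p = 0.0118, adjusted p = 0.996 with an estimated correlation). The list of long noncoding RNAs had 6 of 21 higher and 15 not called (9 higher adjusted over the list alone). ZFAS1, SNHG5, SNHG6 and SNHG15 were among the higher ones (adjusted p = 0.0187 for the list, adjusted p = 0.996 with an estimated correlation). Where in the cell these RNAs lie was not measured. Outside runs of neighbouring genes that shifted together, the long noncoding list was not called (adjusted p = 0.0634) and its median was 0.10 (SD of members 0.38, n = 18) against 0.19 (SD 0.37, n = 21). The proteasome list was not called there either (adjusted p = 0.0554), with its median at 0.078 (SD 0.16, n = 41) against 0.082 (SD 0.21, n = 43). RPL35, RPL7A, NDUFA8, PSMD5, PSMB7 and ISCA1 lie on chromosome 9, whose median gene was higher by 0.50 in 3D1 and 0.48 in IH2. Of 39 JAK-STAT components 2 were higher, OSMR among them, 3 lower, IL10RA and EPOR among them, and 34 not called (6 higher and 8 lower adjusted over the list alone, adjusted p = 0.881). OSMR, a cytokine receptor chain, was 1.02 ± 0.18 CPM in WT1F8, 12.2 ± 1.14 CPM in 3D1 and 9.19 ± 0.605 CPM in IH2.

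**Figure D3:**
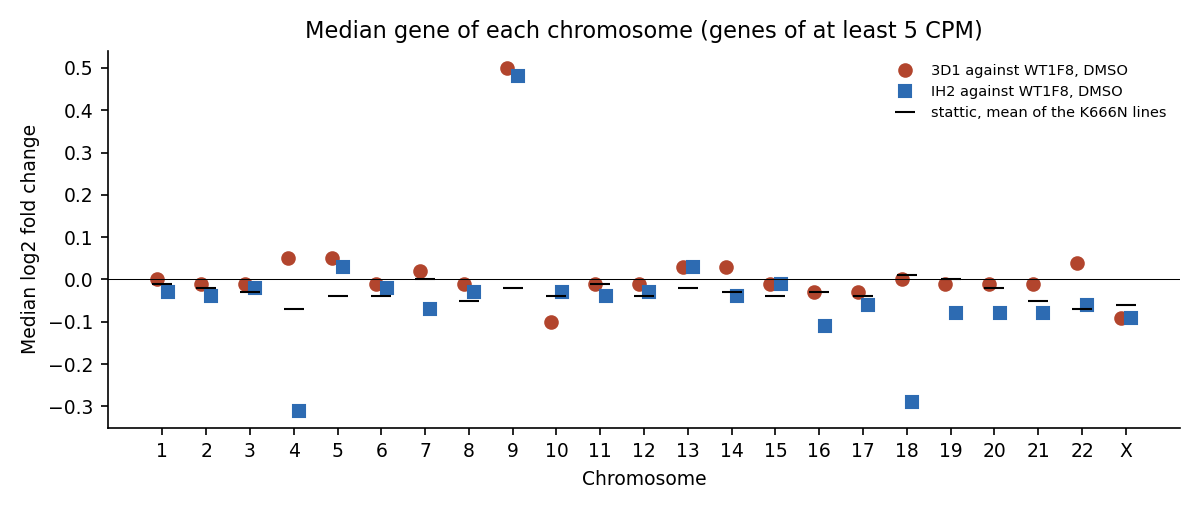
Median log2 fold change (vertical axis) of the genes of at least 5 CPM on each chromosome (horizontal axis). Circles and squares are 3D1 and IH2 against WT1F8 in DMSO and dashes stattic in the K666N lines. Chromosome 9 stands at 0.50 and 0.48 in DMSO.

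In DMSO, 6178 genes differed between 3D1 and WT1F8 (2865 higher, 3313 lower), 7367 between IH2 and WT1F8 (3564 higher, 3803 lower), and 3705 in both in the same direction (1712 higher, 1993 lower), while 124 genes higher in 3D1 were lower in IH2 and 148 lower in 3D1 were higher in IH2. The 2 lines with the same edit differed from each other in 4763 genes (2200 higher and 2563 lower in 3D1). There is 1 control line and 2 edited ones, so these p-values measure the spread of libraries and not of lines. A fit with 1 summed library per line leaves 1 WT1F8 library, so its number of calls cannot judge the difference between lines. DESeq2, run only on separate libraries, called 3855 in both lines. Both comparisons also use the same WT1F8 libraries. Across 10734 genes their fold changes correlated with r = 0.639, against a median of 0.5 in 20 simulations without effects, and the covariance was 0.2067 against 0.0121. Under stattic, 4336 genes differed from WT1F8 in both lines (2161 higher, 2175 lower), with r = 0.675 against 0.496. The simulations hold no differences between lines. A shift of WT1F8 alone would also raise these values above the simulated ones, so the gap does not speak for an effect of the edit. In DMSO 5 lists were called with the preset correlation, 9 without WT1F8 DMSO replicate 1, and 0 with the estimated one. The block on replicate number gave 7465 genes for 3D1, 8617 for IH2, 4503 for both and 6068 between the 2 lines in DMSO, and 5179 for both under stattic. It added glycolysis (adjusted p = 0.039) and hypoxia (adjusted p = 0.0213) to the lists in DMSO.

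The last comparison asked whether the lines responded differently to stattic, by the interaction. CRIP2 (ENSG00000182809.6), which encodes a LIM domain protein, was the 1 gene called in both K666N lines. It was 1.12 ± 0.37 CPM in WT1F8 under DMSO and 1.08 ± 0.356 CPM under stattic, and rose from 1.05 ± 0.162 to 5.37 ± 0.293 CPM in 3D1 and from 2.55 ± 0.38 to 9.62 ± 1.17 CPM in IH2 (differences of log2 fold changes 2.39 ± 0.33 and 1.96 ± 0.32, adjusted p = 0.0225 and 0.0207). In 3D1 the response also differed for ANK3 (0.87 ± 0.13), MME (1.58 ± 0.25), AKAP4 (2.68 ± 0.44) and TMEM158 (1.35 ± 0.22). The differences for ANK3, MME, AKAP4 and TMEM158 in IH2 were 0.18, 0.64, 1.26 and 0.66. None of these was called there (adjusted p = 0.569, 0.263, 0.211 and 0.193). AKAP4 was low, with a mean of 0.509 CPM over all libraries. These 5 genes lie outside the rule and were chosen after their values were seen. CRIP2 lost its call in 10 of 18 fits that left out 1 library. Both interactions share the WT1F8 libraries, and simulations without effects gave up to 1 shared call for them (median 0). The number of shared genes is therefore no larger than these simulations reached. SF3B1, STAT3 and STAT5A were not called.

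The interaction called 5 genes for 3D1 (5 higher, 0 lower, 1846 at an unadjusted p under 0.05), 32 for IH2 (26 higher, 6 lower, 3009 at an unadjusted p under 0.05) and 1 for both (688 at an unadjusted p under 0.05). With the block on replicate number the counts were 26, 130 and 7, and DESeq2 called 108, 417 and 29. Without replicates 1, 2 and 3 in turn the count for 3D1 was 9, 0 and 0 (3D1 DMSO), 0, 33 and 0 (3D1 STATTIC), 5, 2 and 1 (WT1F8 DMSO) and 0, 1 and 0 (WT1F8 STATTIC), and that for IH2 was 11, 2 and 2 (IH2 DMSO), 626, 2 and 17 (IH2 STATTIC), 22, 5 and 7 (WT1F8 DMSO) and 29, 16 and 2 (WT1F8 STATTIC). The larger number of genes called under stattic in the K666N lines is therefore a difference shown for few single genes. With the preset correlation 23 lists differed and with an estimated one 0, and 0 members of any list were called over all genes in both K666N lines. For IH2 alone the list members MT2A (adjusted p = 0.047) and ALAD (adjusted p = 0.0209) were among the 32 genes called. Among the lists immediate early genes were higher in the K666N response by a median of 0.85 (9 higher adjusted over the list alone, adjusted p = 4.88e-07, adjusted p = 0.309 with an estimated correlation). Oxidative phosphorylation genes were lower by a median of -0.28 (6 lower adjusted over the list alone, adjusted p = 1.01e-21, adjusted p = 0.255 with an estimated correlation). The DMSO libraries enter this difference and the comparison in DMSO with opposite sign, and in DMSO this list was higher (median 0.117).

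**Figure D4:**
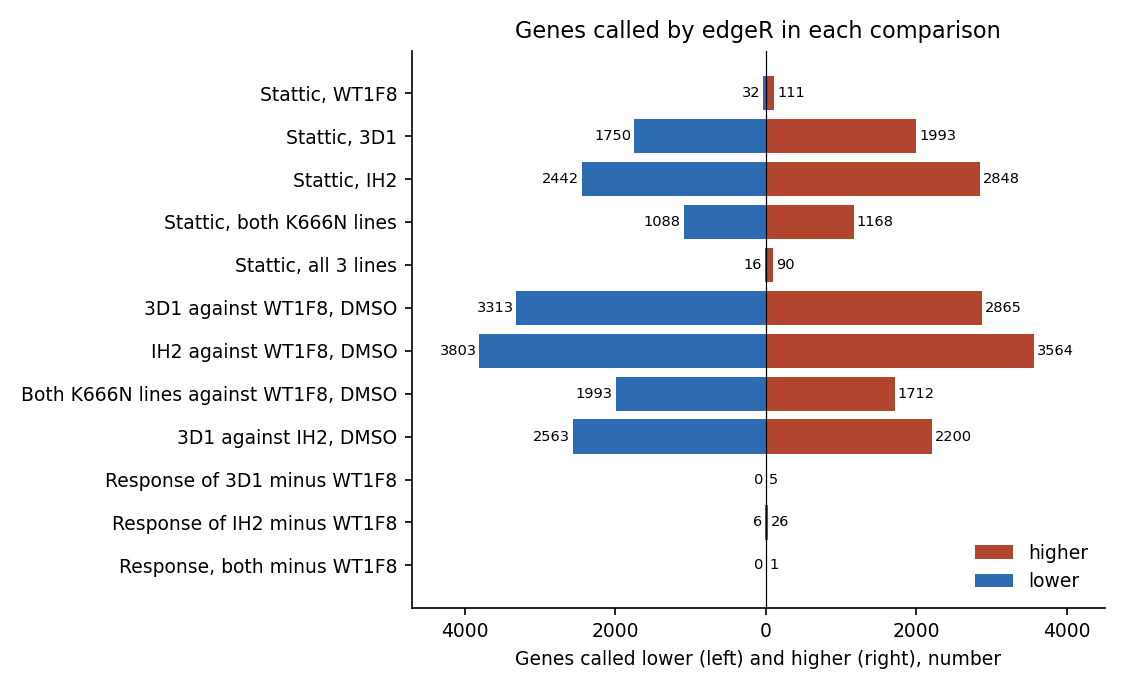
Number of genes called by edgeR (horizontal axis) higher (right) and lower (left) in each comparison (vertical axis). Stattic changed 143 genes in WT1F8, 3743 in 3D1 and 5290 in IH2, while the test of the difference itself called 5, 32 and 1.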

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

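The test of whether IH2 STATTIC replicate 3 makes the K666N response larger was chosen after the result was seen, and the tests of the difference of responses were planned. The interaction of line and compound picked out 5 genes for 3D1, 32 for IH2 and 1 for both. CRIP2 differed by a mean of 2.18 on the log2 scale over both lines. In 3D1 ANK3 differed by 0.87, MME by 1.58, AKAP4 by 2.68 and TMEM158 by 1.35. In IH2 their differences were 0.18, 0.64, 1.26 and 0.66 and were not called. When libraries were reassigned among the lines within each arm, 4 of 100 splits gave as many genes for 3D1, 4 of 100 for IH2 and 2 of 100 for both, the real one included. The highest of the others were 3450, 3489 and 752 genes, many times the real counts, which points to a structure of the samples: these splits mix lines that differ in 6178 and 7367 genes in DMSO. The line differences fix the outcome of such splits, so they cannot exclude chance for these counts.

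For 23 lists the median response differed between the K666N lines and WT1F8 with the preset correlation, and for 0 with the estimated one, where adjusted p ran from 0.14 to 0.686. Higher in the K666N response were metallothioneins (1.65), immediate early genes (0.85), ERK output genes (0.41), fibroblast and epithelial markers (0.37), megakaryocyte genes (0.34), STAT3 targets (0.20), interferon-stimulated genes (0.16), autophagy and lysosome genes (0.15) and hypoxia genes (0.14). Lower were histones (-0.40), mitochondrially encoded mRNAs (-0.31), erythroid genes (-0.29), oxidative phosphorylation genes (-0.28), ribosomal proteins (-0.24), ribosome biogenesis (-0.17) and G1/S genes (-0.16). Also lower were missplicing targets (-0.13), heme synthesis (-0.12), serine synthesis (-0.12), long noncoding RNAs (-0.12), the spliceosome (-0.10), DNA repair (-0.09) and the proteasome (-0.08). In the same splits 1 of 100 gave as many lists, the real one, and the highest other gave 21, which excludes chance no more than above. Without IH2 STATTIC replicate 3 the hypoxia list was not called (adjusted p = 0.13). The DMSO libraries enter this difference and the comparison in DMSO with opposite sign. A shift of those libraries alone would move both. Ribosomal proteins had medians of 0.248 in DMSO and -0.243 in the response, and oxidative phosphorylation genes 0.117 and -0.276. The proteasome had 0.082 and -0.08, and long noncoding RNAs 0.194 and -0.121. Erythroid genes were lower in both (-0.598 and -0.289). These results are therefore not independent.

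A pattern that may lie behind these values is a larger response to stattic in the K666N lines. Across 10734 genes the major axis (first principal axis) of the 3D1 response against that of WT1F8 had a slope of 1.87. That value uses no IH2 library, and the slope for IH2 without STATTIC replicate 3 was 2.06, so that library is not the whole source of the steep slopes. A major axis steepens with any added spread in the K666N line. An ordinary regression slope would be lower and was not computed, so these slopes alone do not show a larger response. Handling that differed between replicate numbers stays open: over 3116 genes, selected as called under stattic in IH2 and read in the direction of that call, the 3D1 response exceeded that of WT1F8 in 3 of 3 replicate numbers, by 0.026, 0.206 and 0.346 (mean 0.19, SD 0.16), so the excess may be of the size of its spread. WT1F8 STATTIC replicate 1 stands apart, with a WT1F8 response of 0.286 there against 0.158 and 0.162 (0.312 in 3D1), HSPA6 at 28.8 CPM against 5.99 and 7.14, and CRYAB at 37.3 against 8.85 and 5.68. An effect of the SF3B1 edit is also open and untested, since WT1F8 is the only control line.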

How the results depend on the processing

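The fits without a replicate number, with robust spread, without factors, and without IH2 STATTIC replicate 3 plus the block on replicate number were chosen after the data were seen. With 1 control line and 3 libraries a group, the spread measured is that of libraries and not of lines. RLE factors, no factors and robust spread moved no total number of genes or lists by over 1.5 times, but without factors the split into higher and lower moved. Without factors the median gene under stattic in 3D1 stood at 0.148 against 0.017, in both K666N lines at 0.115, and between 3D1 and IH2 in DMSO at -0.121, and of the genes called, 79.6% were higher in 3D1 against 53.2%, 64.8% in IH2 against 53.8%, 70.6% by the mean of both K666N lines against 52.6%, 86.1% in WT1F8 against 77.6%, and 28.6% between 3D1 and IH2 in DMSO against 46.2%. The balance of higher and lower genes is therefore relative to the TMM scale. The block on replicate number ended no call of a gene followed here, added STAT3 in WT1F8 (adjusted p = 0.0189) and changed no other call of these genes. It added the lists hypoxia (adjusted p = 0.0464), unfolded protein response (0.046) and NF-kB targets (0.0456) for stattic in the K666N lines, glycolysis (0.039) and hypoxia (0.0213) in DMSO, and for the response BCL2 family genes (0.0247), the unfolded protein response (0.0377), NF-kB targets (0.0377) and G2 genes (0.0489). Of the calls of the 143, 2256 and 106 genes for stattic in WT1F8, both K666N lines and all 3 lines, 143, 2254 and 106 were kept under the block. Over 187 gene values and their alternatives, 1390 kept direction and side of the threshold, 86 lost the call, 4 gained it and 7 reversed. Of the 86, 34 came with only the libraries of the comparison, 27 at the lowest and 20 at the highest value with a library left out, 4 without a low-count filter (ALAD, PSMD6, SNHG15, STAT3) and 1 with RLE factors (PTPN6, adjusted p = 0.0523). The cause was not tested except where fewer samples or genes are the alternative's own construction.

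Estimated correlation: 0 lists in each of the 4 comparisons. A single summed library per line: WT1F8 is then 1 library in an arm, so numbers of calls are not read from these fits. Replicate block: 648 genes for stattic in WT1F8, 447 in all 3 lines, 3392 in both K666N lines, and 26, 130 and 7 for the response of 3D1, IH2 and both. DESeq2: 611 in WT1F8, 401 in all 3 lines, and 108, 417 and 29 for the responses. At least 1 CPM in 3 libraries: 217 in WT1F8 and 160 in all 3 lines. No low-count filter: 787, 518, and 271, 912 and 107 for the responses. Only the libraries of the comparison: 2 in WT1F8, and 1 and 2 for the responses of 3D1 and IH2. Without IH2 STATTIC replicate 3 and with the block: 1122 in WT1F8, 723 in all 3 lines, 6603 in 3D1, and 111, 93 and 17 for the responses.

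Leaving out 1 library or 1 replicate number gave 1 to 269 genes for stattic in WT1F8 (3, 29 and 1 without replicate numbers 1, 2 and 3), 313 to 4816 in 3D1, 1155 to 6190 in IH2, 189 to 2710 in both K666N lines and 1 to 179 in all 3 lines. In DMSO it gave 3335 to 6428 genes for 3D1 against WT1F8, 4638 to 6838 for IH2, 2036 to 3526 for both and 2090 to 5343 for 3D1 against IH2, and under stattic 2486 to 4440 for both. For the responses it gave 0 to 33, 0 to 626 and 0 to 5 genes. For lists in DMSO it gave 4 to 9. With 2 replicate numbers each group keeps 2 libraries.

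Values that were not called and changed sign were SF3B1 in DMSO (-0.097 to 0.023 with a library left out), SF3B1 in the response (-0.070 to 0.081 with a library left out, -0.021 without a filter), STAT3 in the response (-0.005 to 0.13 with a library left out), and STAT5A in DMSO (0.007 with at least 1 CPM, 0.001 with only its libraries, -0.051 to 0.079 with a library left out).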

Other observations

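The tests of the heat shock and immediate early genes of IH2 STATTIC replicate 3 on those genes alone were chosen after the first tests of that library were seen. Other lists were called under stattic in the K666N lines with the preset correlation only. Of 11 metallothionein and zinc export genes 1 rose and 10 were not called (7 higher and 1 lower adjusted over the list alone), and MT2A, a metal-binding protein gene, rose from 29.2 ± 3.32 to 81.4 ± 17.3 CPM in 3D1 and from 52.0 ± 2.71 to 231 ± 57.2 CPM in IH2 (adjusted p = 0.0439 for the list, adjusted p = 0.418 with an estimated correlation). Of 19 fibroblast and epithelial markers 2 rose, the keratin KRT19 (1.06 ± 0.11) and the actin-binding TAGLN (1.09 ± 0.12), and 17 were not called (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.0195, adjusted p = 0.221 with an estimated correlation). Of 49 ATF4 genes 4 fell, MTHFD1L, CBS and SHMT2 among them, and 45 were not called (18 lower and 5 higher adjusted over the list alone, adjusted p = 0.000297, adjusted p = 0.478 with an estimated correlation). Of 13 mitochondrially encoded mRNAs none was called by edgeR over all genes in both lines (5 lower adjusted over the list alone, median -0.30, adjusted p = 0.00277, adjusted p = 0.422 with an estimated correlation). Of 43 proteasome genes 2 fell, PSMD6 among them, and 41 were not called (18 lower adjusted over the list alone, adjusted p = 0.00119, adjusted p = 0.418 with an estimated correlation).

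Neighbouring genes moved together in the K666N lines against WT1F8 in DMSO. On chromosome 9 the 420 genes of at least 5 CPM had medians of 0.50 in 3D1 and 0.48 in IH2, and 56.2% were higher in both lines. A run of 329 genes from SHB to EHMT1 had a median of 0.61 in 3D1, and a run of 326 genes from FRG1JP to EHMT1 a median of 0.56 in IH2. In IH2 81 genes of chromosome 18 from DSG2 to ADNP2 had a median of -0.60 and 230 genes of chromosome 4 from FIP1L1 to FRG1 a median of -0.47. In 3D1 there were runs on chromosome 4 from ZNF721 to MFSD10 (34 genes, -0.48) and from SAP30 to FRG1 (26 genes, 0.38) and on chromosome 10 from KAT6B to HELLS (51 genes, -0.45) and from BMS1 to ADO (37 genes, -0.27). On the X chromosome 105 genes in 3D1 had a median of -0.29 and 68 genes in IH2 a median of -0.31, and shorter runs lay on chromosomes 7, 16 and 19. Of the 3705 genes called in both lines, 432 lay in such runs and 3273 outside. Medians of this kind are what a different number of chromosome copies would give, but gene counts alone do not measure copies.

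The idea that copies account for the higher lists in DMSO came from seeing named genes on chromosome 9, and the tests below were set before their results. Ribosomal proteins outside the shifted chromosome had a median of 0.244 (adjusted p = 6.25e-09), and the median of the whole list kept 87.7% of its size after a trend with GC content and length was removed, which argues against both as the whole cause. Oxidative phosphorylation genes outside it had 0.117, and 64.1% was left after the GC and length trend, so that trend may account for a part. For the proteasome 98.3% was left after the GC and length trend. Its genes outside chromosome 9 had 0.078 (adjusted p = 0.0311) against 0.082 for all, but the bound of 0.1 lay above the whole median, so this test could not argue against copies and is not used. Outside the runs above, the median of its 41 members was also 0.078 (SD of members 0.16, against 0.21 for all 43), though the list was not called (adjusted p = 0.0554), and copies stay open for it because no test here could exclude them. Chance is not excluded for the number of lists, since 87 of 100 splits of the DMSO libraries gave at least the real 5 (highest other 23), and an effect of the edit was not tested.

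IH2 STATTIC replicate 3 held HSPA1A at 5290 CPM against 442 and 1280 in replicates 1 and 2, HSPA1B at 6580 against 444 and 1310, DNAJB1 at 1410 against 209 and 417, and FOS at 309 against 14.8 and 37.0. HSPA1A and HSPA1B are near-identical copies. A library of another line, or a mixture with one, would lie toward that line, but it lay 9.4% of the way toward WT1F8 and 5.7% toward 3D1. The limit of 10 was written before the result, and 9.4 lies closer to it than the spread between replicates 1 and 2 (-2.9), so this value alone decides nothing. During the work the first 2 tests of this library were replaced after their results were seen, then restored word for word, and the replacements are the later 2 tests. Of the 29 heat shock and immediate early genes more than 1 log2 higher in it, 100% were above every library of the other lines, which a mixture alone could not give. These genes were selected as high in this library, so a partial mixture beside another cause is not excluded. Across 10734 genes the deviation of this library correlated with the 3D1 response at 0.03. By the limit set beforehand this argued against a stronger response of the whole culture. Principal components 1, 2 and 3 went the other way. On components 1, 2 and 3 this library lay at 84.56, 63.89 and 38.49, further from IH2 in DMSO than replicate 2 (81.86, 48.97, 18.64) and replicate 1 (77.49, 40.05, 1.3). On component 4 it lay at 52.94, against -18.97 and 3.1 in replicates 1 and 2. The highest other library there was 3D1 DMSO replicate 2 at 26.68, so this library also departed in a way of its own. A stronger response of the whole culture is therefore neither shown nor excluded. Over the 59 heat shock and immediate early genes, chosen after the value of 0.03 was seen, the correlation was 0.54. A stronger response of these genes alone is thus a hypothesis, and handling of that 1 culture is not excluded.

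Other splits of the libraries gave the following. For stattic in WT1F8, 3D1 and IH2, each with 10 splits of 6 libraries, the real one gave 143, 3743 and 5290 genes and the highest other 0, 0 and 2. For 3D1 against WT1F8, IH2 against WT1F8 and 3D1 against IH2 in DMSO the real splits gave 6178, 7367 and 4763 and the highest others 0, 1 and 0. With 10 splits the share cannot fall under 0.05. For the lists of WT1F8, 3 of 10 splits gave at least the real 16, and the highest, 18, came from a split that also parts all 3 replicate numbers. Of 100 splits, the real one alone gave 2256 genes for stattic in both K666N lines and 106 in all 3 lines (highest other 0 each). These splits shuffle all 3 lines at once and put the stattic effect into the spread. They therefore argue only against no stattic effect in any line, and do not exclude chance for a single line or for the size of these counts. For both lines against WT1F8, in DMSO (1 of 100, 3705, highest other 2196) and in stattic (1 of 100, 4336, highest other 3420), the splits exchange lines that differ, which fixes their outcome. They do not exclude chance between lines. For the lists of stattic in the K666N lines chance is not excluded, with 16 of 100 splits giving at least 24 and a highest of 28.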
